A study of Mus musculus with 9 samples.

How the data were processed

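Single-cell RNA sequencing was carried out on left lungs of 3 groups, with 3 libraries each that the study's description calls biological replicates. BI lungs were transplanted and treated with baicalein, a plant flavonoid. IR lungs were transplanted and left untreated, as a model of injury by ischemia and reperfusion. Sham lungs came from a sham operation, although the tissue label of these libraries names a transplanted lung as well. Groups were taken from the treatment label and replicate numbers from the titles.

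The deposited values are integer counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, in 1 sparse matrix per library. Per the file headers, the matrices were written by PISA 1.0. The submitters' processing notes name STAR and the human build GRCh38, with no version of STAR, while the labels name mouse as the organism and the description names rats. The gene lists hold rat names: 32 begin with RT1-, the rat major histocompatibility complex, and 3882 are rat Ensembl identifiers, beside 2541 LOC names. Genes were therefore read as rat genes under the names in the files, with no coordinates. The mouse reference genome was not used here. The kit named in the protocol (DNBelab C4) differs from the platform named elsewhere in the labels (10x Genomics). The lungs were digested with trypsin and DNase I, red cells were lysed and the suspension was strained. The annotation and the filters behind the barcodes are not given in the sources used here.

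The 9 libraries held 105337 barcodes, each with at least 1000 UMIs, against 83590 cells that the study kept after Seurat and a doublet tool. The study's own cell annotation was not used here. Barcodes with at least 200 genes and at most 25% of UMIs from 13 mitochondrial genes were kept (104334). Scrublet scores were computed per library with scanpy. Its automatic threshold called only 8 cells, so the top 5% of scores in each library (5221 cells) were removed instead, a choice made after the data were examined, which left 99113 cells. The feature lists differed between libraries, with 26314 genes in any and 18116 in all, and a gene missing from a list was counted as 0 there. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes among those seen in at least 20 cells gave 30 principal components, a graph of 20 nearest neighbours (at least 3 shared) and Leiden clusters at resolution 1, with no integration across libraries (seed 1). Each of 49 clusters was named from 202 markers of 21 cell classes, of which 181 matched a gene in the files. A name needed at least 3 markers seen in at least 10% of the cluster's cells, a mean z score of at least 0.4 (pseudocount 5 CPM), a runner-up under 60% of it, at least 20 cells and fewer than 25% of doublet calls. The neutrophil class was not counted as a runner-up. Cluster 1, named monocyte- or interstitial macrophage-like at a z score of 0.915 (neutrophil 0.6823), and cluster 44, named B-like at 2.263 (neutrophil 1.682), would otherwise have stayed unnamed. These limits were set after the data were examined. They named 34 clusters and left 4184 cells unnamed, a mean of 3.17% of BI, 1.99% of IR and 5.72% of Sham cells, which stayed in the denominators. Classes are called "-like" because they rest on markers alone.

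Shares of cells were compared with edgeR's quasi-likelihood test on cells per class and library, with the log of all kept cells as offset. A two-sided exact permutation test of each share stood beside it, whose smallest p with 3 libraries against 3 is 0.1. For gene tests, UMIs were summed over the cells of a class in each library, where the library held at least 20 of them, and 12 classes had at least 2 such libraries in every group. Sums were tested with edgeR (TMM factors, filterByExpr, quasi-likelihood) over all libraries at once for BI minus IR, IR minus Sham and BI minus Sham. P-values were adjusted by the Benjamini-Hochberg (BH) method within a contrast, with 0.05 as the threshold. Log2 fold changes (log2FC) carry the fit's standard error (SE), and mean CPM values, scaled to the library total times its TMM factor, are over 3 libraries per group unless stated. Fold changes against a group with no UMI are given as bounds, against 3 counts over the group. They cover counting error only. CPM over all cells, those of S100a9 in endothelial-like cells and others where said are scaled to the plain library total.

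There were 15 gene lists: AGE-RAGE signalling, RAGE ligands, inflammatory cytokines and NF-kB targets, neutrophil granule proteins, neutrophil recruitment, interferon response, hypoxia and glycolysis, heat shock and immediate early genes, NRF2 and oxidative stress, eicosanoid enzymes, inflammasome, class II antigen presentation, cytotoxic effectors, cell cycle and mitochondrial-encoded genes. Lists with at least 5 tested members were tested with limma's camera on voom values (preset correlation 0.01; prior count 2) in 7 classes, with an estimated correlation and fry beside it, and BH over the lists. The difference of the BI minus IR effect between neutrophil-like and monocyte-like cells was tested with limma on each library's difference of log2 CPM. Genes were named by rule: for neutrophil-like cells, the 8 largest rises and 8 largest falls among genes past the threshold with at least 32 CPM and no overlap between the groups, up to 4 members of each list with the smallest p, and 11 genes whatever their p. Of these 11, Hmgb1 was not tested, with 26 UMIs in all neutrophil-like cells. Other classes took the 4 largest rises and falls. LOC names, clone names, ribosomal, mitochondrial and globin genes were left out of the ranked part. Groups, tests, markers, lists, the rule for named genes and most alternatives were fixed before the data were examined.

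The tests were checked on simulated data with known changes, for BI minus IR, at 50 changed genes per fold size. In neutrophil-like cells (7450 genes) 26%, 76%, 98% and 96% of genes changed 1.5-, 2-, 4- and 8-fold were found, with 7 false calls. In T-like cells (10276 genes) 60% were found at 2-fold and 94% at 4-fold, and in endothelial-like cells (7733 genes) only 6% and 42%. For shares, 88% of classes raised 4-fold were found, with 1.87% false calls over 18 classes and 50 simulations. The other classes and the cell totals were left unchanged in these simulations. They therefore cannot show how often a class is called only because another class changes. For the difference between classes, 67.5% of 200 genes changed 4-fold in neutrophils alone were found among 6239, with 1 false call. The hypoxia list, raised 1.5-fold in neutrophil-like cells over 7450 genes, was called with no other list. Genes were drawn independently of each other there, so this cannot show lists called through correlation between their genes.

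Alternatives were DESeq2, median-ratio (RLE) factors, no filter on low counts, a replicate block, a fit of only the 6 libraries compared, stricter cells (at least 500 UMIs and at most 10% mitochondrial), other doublet treatments, other resolutions (0.5 and 2), equal cell numbers, thinned counts, other denominators and each library left out in turn. Chosen after seeing the data were leaving out genes at the level of free RNA (CPM in the class under 0.25 of that over all cells), cells of at least 2000 UMIs, a denominator without neutrophils, doublets at 0.8% per 1000 cells (11866 cells), neutrophil cluster 0 alone, macrophages without clusters 5 and 8 (for genes, and for shares with these clusters unnamed), both libraries with the fewest neutrophils left out, different IR libraries in each contrast for opposite calls, lymphocyte interferon genes with an IR level under 0.25 of, or under, that over all cells left out, and, for the other classes and the difference between classes, leaving out each library, an estimated correlation and the block. Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.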

Results

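RNA of single cells was counted in left lungs of 3 groups of rats: baicalein-treated transplants (BI), untreated transplants with ischemia-reperfusion injury (IR) and sham-operated animals (Sham), with 3 libraries per group. The libraries held 20996732 to 38821742 UMIs in BI, 42399565 to 48561537 in IR and 56605827 to 85567767 in Sham. After filtering, 4719 to 6554 cells per BI library, 9170 to 9544 per IR library and 16262 to 20844 per Sham library were kept, with library medians of 2213 to 3632 UMIs per cell. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 35.5 to 258). The median share of mitochondrial UMIs lay between 0.0893% and 0.221% in the BI and IR libraries and between 0.553% and 1.37% in the Sham libraries.

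The first question was which cells filled the untreated and the treated graft. Neutrophil-like cells made up 52.1% ± 5.52 of cells in IR, 8.80% ± 7.24 in BI and 3.35% ± 2.89 in Sham (mean ± SD, n = 3). Their share fell from IR to BI (log2FC -2.57, SE 0.745, adjusted p = 0.00948 by edgeR) and was the only one of 18 classes called lower. In the 3 BI libraries it was 16.9%, 3.01% and 6.46%, against 55.6%, 55.0% and 45.8% in IR. Structural and lymphoid cells took larger shares in BI: endothelial-like cells rose from 0.284% ± 0.0713 to 2.98% ± 0.557 (log2FC 3.39, SE 0.347, adjusted p = 1.33e-05). Fibroblast-like cells rose from 0.111% ± 0.0268 to 1.54% ± 0.304 (log2FC 3.78, SE 0.497). T-like cells rose from 3.69% ± 0.736 to 14.8% ± 3.52 (log2FC 2.01, SE 0.335). B-like cells rose from 1.75% ± 0.534 to 8.87% ± 1.88 (log2FC 2.34, SE 0.343) and NK-like cells from 2.62% ± 0.363 to 9.17% ± 1.30. Smooth muscle-like (log2FC 3.08), alveolar type 2-like (2.98), alveolar type 1-like (1.71), dendritic-like (1.59) and airway epithelial-like cells (1.23, adjusted p = 0.0349) rose too. Alveolar macrophage-like cells (6.65% in IR, 7.50% in BI) and monocyte- or interstitial macrophage-like cells (27.2% and 34.9%) did not pass the test. The libraries of BI and IR did not overlap for the 11 classes called (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

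Shares add up to a whole, so a fall of 1 large class raises the others. With neutrophil-like cells left out of the denominator, a choice made after seeing the data, 6 classes passed in BI against IR, and the airway, alveolar type 1-, alveolar type 2- and dendritic-like classes no longer did. With immune cells alone as denominator 5 passed. The test on the share of airway epithelial-like cells, BI minus IR, did not pass without BI replicate 2 (adjusted p = 0.095), BI replicate 3 (0.0569), IR replicate 2 (0.121) or IR replicate 3 (0.0936). Under TMM factors over the class counts, 2 classes were called higher and 6 lower in BI than in IR, and the log2FC turned negative for NK-like (-0.30), T-like (-0.08), dendritic-like (-0.56), alveolar type 1-like (-0.40) and airway-like cells (-0.92).

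**Figure D1:**
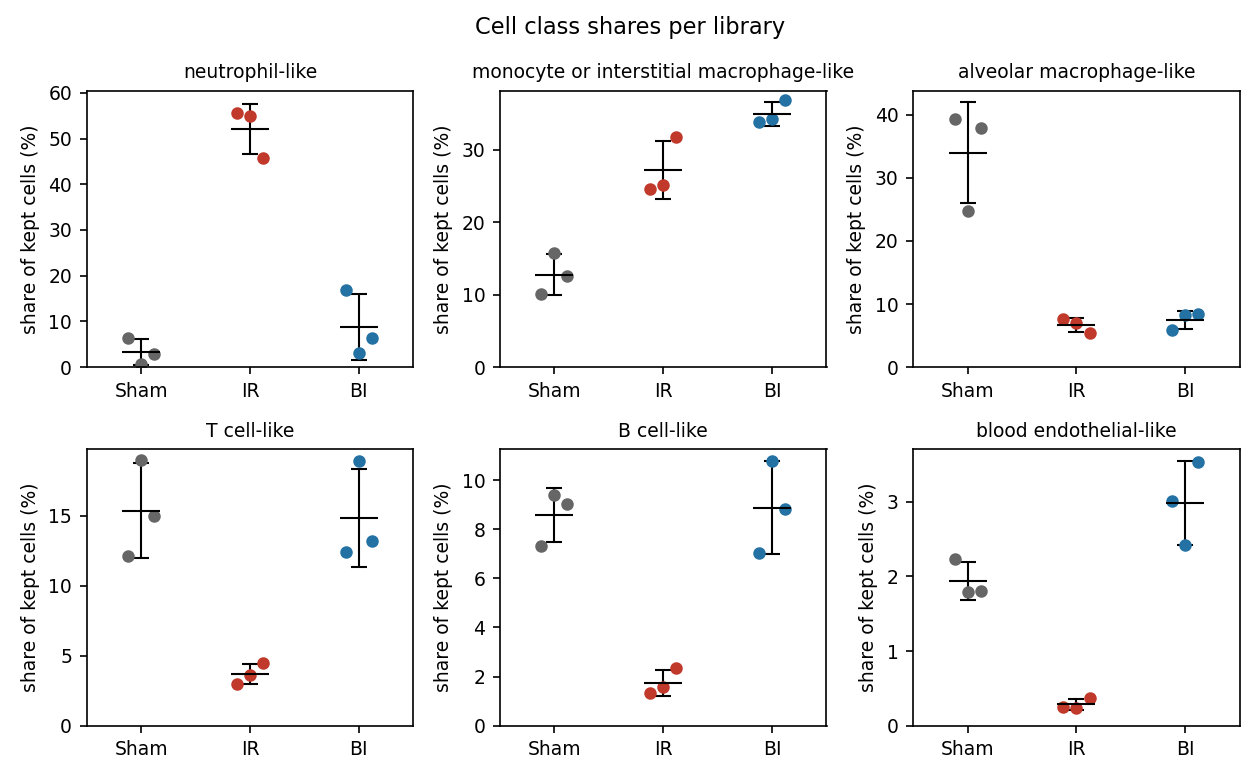
Share of kept cells (percent, vertical axis) in the Sham, IR and BI libraries (horizontal axis). Panels show neutrophil-, monocyte- or interstitial macrophage-, alveolar macrophage-, T-, B- and endothelial-like cells. Points are libraries, with the group mean and SD. Neutrophil-like cells reach 45.8% to 55.6% in IR and at most 16.9% in BI.

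The untreated graft held larger shares of neutrophil- and monocyte-like cells than Sham and smaller shares of most other classes. From Sham to IR, neutrophil-like cells rose from 3.35% to 52.1% (log2FC 3.96, SE 0.792, adjusted p = 0.000661) and monocyte-like cells from 12.8% ± 2.82 to 27.2% ± 3.99 (log2FC 1.09, adjusted p = 0.00534). The other 14 classes called fell, among them alveolar macrophage-like cells from 34.0% ± 7.99 to 6.65% ± 1.15 (log2FC -2.35, adjusted p = 8.54e-05), endothelial-like cells (log2FC -2.76) and T-like cells from 15.4% ± 3.42 (log2FC -2.06). Without Sham replicate 1 the calls of alveolar type 2-like (adjusted p = 0.109) and alveolar type 1-like cells (0.0512) ended. That of plasmacytoid dendritic-like cells ended without IR replicate 2 (0.0779), IR replicate 3 (0.0757) or Sham replicate 2 (0.105). Clusters 5 and 8 held 33.0% and 21.9% of the alveolar macrophage-like class in Sham. With them left unnamed, a choice made after seeing the data, the log2FC was -1.20 (adjusted p = 0.0067) for the share of alveolar macrophage-like cells, IR minus Sham, and -1.11 (adjusted p = 0.0345) for the share of alveolar macrophage-like cells, BI minus Sham. The monocyte-like rise was not called at the lower clustering resolution (log2FC 0.26, adjusted p = 0.387), and with TMM factors 4 classes were higher and 3 lower. These factors turned the sign for alveolar type 1-like (0.41), dendritic-like (0.78), NK-like (0.47) and plasmacytoid dendritic-like cells (0.63). Fewer classes were called between the treated graft and Sham, but the differences were not smaller in all of them. Monocyte-like cells were higher (log2FC 1.45, adjusted p = 0.00283, against 1.09 in IR). Alveolar macrophage-like (-2.18, against -2.35 in IR), plasma cell-like (-1.82), airway-like (-1.36, adjusted p = 0.0401) and mesothelial-like cells were lower. The airway-like class was not called without BI replicate 1 (adjusted p = 0.117), BI replicate 3 (0.136), IR replicate 3 (0.0698), Sham replicate 1 (0.0749) or Sham replicate 2 (0.135), nor the plasma cell-like class without BI replicate 1 (0.072), BI replicate 3 (0.0761) or Sham replicate 2 (0.0663). No mesothelial-like cell was seen in BI. Neutrophil-like cells in BI did not differ from Sham by the test (log2FC 1.39, SE 0.718, adjusted p = 0.174; two-sided exact permutation p = 0.2), but without Sham replicate 1 they did (log2FC 2.29, adjusted p = 0.0487). Without BI replicate 1, BI replicate 3 or Sham replicate 2, only 3 classes passed in BI against Sham.

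The study centres on neutrophils, and BI minus IR asks how those that remained differed. Neutrophil-like cells of the treated graft held less RNA of cytokines, of the iron-binding protein Lcn2 and of the receptor Trem1 that amplifies neutrophil activation. In all, 647 genes were higher and 724 lower in BI among 7450 tested. Trem1 fell from 4018 to 1469 CPM (log2FC -1.45, SE 0.150, adjusted p = 2.99e-06) and Lcn2 from 2668 to 649.5 CPM (log2FC -2.06, SE 0.214, adjusted p = 2.99e-06). Csf3, the growth factor that drives granulocyte production, fell from 52.0 to 7.48 CPM (log2FC -2.41, SE 0.264, adjusted p = 3.72e-06). Csf3 was also among the top 10 genes of the monocyte-like cluster 1. The largest falls were those of Retn (resistin, log2FC -5.76), RT1-A2 (a class I histocompatibility gene, -3.93), Ngp (a granule protein, -2.88), the scavenger receptor Msr1 (-2.44), Saal1 (-2.20), Agpat4 (-1.98) and Car4 (-1.78). RT1-A2 has close copies in the rat genome, so its counts are uncertain. Over all cells it averaged 9.80 CPM in Sham, 538 in IR and 205 in BI. A strain or donor difference between the animals cannot be told apart from injury or treatment for this gene. The largest rises were those of Sftpc (2.45), Rn7sl1 (2.18), Dgkg (2.07), Tex2 (1.90), Rn18s (1.74), Klrb1b (1.70), Treml4 (1.62) and Cd79a (1.56). Sftpc and Cd79a mark alveolar type 2 and B cells, and Rn18s over all cells averaged 10248 CPM in BI, 3002 in IR and 3061 in Sham.

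Of 33 measured inflammatory cytokines and NF-kB targets, 21 fell and 1 rose in BI against IR (22 and 1 adjusted over the list alone; median log2FC -0.60; camera, adjusted p = 2.4e-10, and adjusted p = 0.340 with an estimated correlation). The neutrophil attractants Cxcl1 (log2FC -1.35, SE 0.150) and Ccl3 (-1.23, SE 0.152) fell with Nfkbia, the NF-kB inhibitor and target (-1.14), and with Il1a (-1.19) and Il1b (-0.67, SE 0.142, adjusted p = 0.00246). Tnf fell from 99.9 to 52.8 CPM (log2FC -1.17, adjusted p = 0.000507), but its log2FC was 0.32 with counts thinned to the smallest library. Among 13 inflammasome genes 4 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.0279, and adjusted p = 0.404 with an estimated correlation), including the inflammatory caspases Casp1 (log2FC -1.79, SE 0.219) and Casp4 (-1.81) and the membrane-rupture protein Ninj1 (-0.62). This list's adjusted p was 0.0997 without BI replicate 1. Of 18 granule genes 4 fell and 0 rose (4 and 0 over the list alone), with Elane (log2FC -0.96) and Anxa1 (-0.62) beside Lcn2 and Ngp (adjusted p = 0.0175, and adjusted p = 0.557 with an estimated correlation). Of 25 interferon response genes 7 fell, among them Ifit3 (-0.69), Ifi47 (-0.76) and the regulator Irf7 (-0.63), and Oas2 rose (1.18). Adjusted over the list alone, 10 fell and 1 rose (adjusted p = 0.00449, and adjusted p = 0.557 with an estimated correlation). Without BI replicate 1 the calls of Ninj1 (adjusted p = 0.0506), Anxa1 (0.0537) and Oas2 (0.372) ended, and without IR replicate 1 that of Anxa1 (0.0575).

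Genes of antigen presentation and of cytotoxic cells were higher in neutrophil-like cells of BI than of IR. Of 10 class II genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.00922, and adjusted p = 0.557 with an estimated correlation), with Cd74 at log2FC 0.81, RT1-Db1 at 0.82, RT1-Ba at 0.71 and RT1-Bb at 0.69. Of 8 cytotoxic genes 6 rose and 1 fell (7 and 1 over the list alone, adjusted p = 0.000737, and adjusted p = 0.545 with an estimated correlation), among them the granzymes Gzmm (1.94) and Gzmb (1.34), the chemokine Ccl5 (1.24) and Nkg7 (1.56). These calls ended for Nkg7 (adjusted p = 0.0878), RT1-Db1 (0.116), RT1-Ba (0.0907) and RT1-Bb (0.0856) without BI replicate 1, for RT1-Ba (0.0642) and RT1-Bb (0.0755) without BI replicate 3, and for Cd74 (0.0563), RT1-Db1 (0.0649), RT1-Ba (0.0873) and RT1-Bb (0.097) without IR replicate 2. Both groups hold markers of other cells, and the share of B-, T- and NK-like cells in the suspension was higher in BI. Of 12 mitochondrial-encoded genes 1 fell, Mt-co1 (log2FC -0.77; 1 over the list alone, adjusted p = 0.0279, and adjusted p = 0.623 with an estimated correlation). The call of the list mitochondrial-encoded in neutrophils, BI minus IR, was lost without BI replicate 1 (adjusted p = 0.140) and without IR replicate 3 (adjusted p = 0.0605), and that of Mt-co1 without BI replicate 1 (adjusted p = 0.114).

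The AGE-RAGE list, named by the study for these samples and so no independent evidence, split in both directions: of 63 measured members 11 rose and 7 fell (13 and 8 adjusted over the list alone, adjusted p = 0.726). Ccl2, a monocyte attractant, fell (log2FC -1.56, SE 0.210), while Foxo1 (2.01) and Col4a1, a basement membrane collagen (2.27), rose. The shares of endothelial-like (log2FC 3.39) and fibroblast-like cells (3.78) were higher in BI as well. Whether the Col4a1 RNA came from such cells was not tested. None of 5 RAGE ligands passed (0 over the list alone as well, adjusted p = 0.726). S100a8 averaged 60348 CPM in IR and 54460 in BI (log2FC -0.15, SE 0.184, adjusted p = 0.629), and S100a9 83590 and 74849 CPM (log2FC -0.16, SE 0.152, adjusted p = 0.507). Scaled to the plain library total instead, S100a8 averaged 48539 CPM in IR and 48808 in BI, and S100a9 67247 and 67125 CPM. Both log2FC turned positive with thinned counts (0.05 and 0.03). The receptor gene Ager rested on 225 UMIs in IR and 41 in BI (log2FC 0.79, SE 0.347, adjusted p = 0.116), too few to detect a small change. Icam1 (log2FC -0.36, adjusted p = 0.142), Stat3 (0.13), Nfkb1 (0.03), Mapk14 (0.42, adjusted p = 0.0652) and Cybb (-0.08) did not pass, and thinned counts turned the sign for Icam1 (0.23) and Cybb (0.03). Icam1 passed without BI replicate 2 (log2FC -0.57, adjusted p = 0.0112).

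The 6 other lists did not pass in BI against IR. Of 27 hypoxia and glycolysis genes 4 rose and 6 fell (6 and 9 over the list alone, adjusted p = 0.303), with the glucose transporter Slc2a1 lower (log2FC -0.85) and the kinases Hk2 (0.94) and Pfkfb3 (1.02) higher. Of 25 NRF2 and oxidative stress genes 1 rose and 4 fell (the same over the list alone, adjusted p = 0.0983), with Sod2 (-0.87), the ferritin chain Fth1 (-0.80) and Hmox1 (-1.20) lower and Gsr (0.72) higher. Among 26 heat shock and immediate early genes 5 rose and 5 fell (5 and 6 over the list alone; median log2FC 0.01, mean 0.13, test direction downward, adjusted p = 0.726), with Hspb1 higher (2.43) and Zfp36, Klf2 and Klf6 lower (-1.04, -1.16 and -0.84). Of 20 recruitment genes 2 rose and 2 fell (2 and 3 over the list alone; median 0.03, mean 0.01, test direction downward, adjusted p = 0.756), including the selectin ligand Selplg (0.56), Itga4 (1.29) and Cd44 (-0.47). Of 10 eicosanoid genes the lipoxygenase Alox15 rose (2.82, SE 0.318) and Ptges3 (-0.70) and Alox5ap (-0.45) fell (1 and 2 over the list alone, adjusted p = 0.726). Of 6 cell cycle genes 2 rose and 1 fell (adjusted p = 0.346), Hmgb2 (1.51), Mki67 (1.80, on 15 UMIs in BI) and Pcna (-0.67). Several of these calls ended when a library was left out. Without BI replicate 1 they were Pfkfb3 (adjusted p = 0.119), Gsr (0.213), Selplg (0.0639), Ptges3 (0.0664), Alox5ap (0.151) and Mki67 (0.316), without BI replicate 2 Cd44 (0.101) and Mki67 (0.0682), and without BI replicate 3 Cd44 (0.163), Itga4 (0.0613) and Alox5ap (0.0853). Without IR replicate 1 they were Cd44 (0.0943), Alox5ap (0.102) and Mki67 (0.0621), without IR replicate 2 Cd44 (0.132), Selplg (0.0625), Ptges3 (0.0568), Alox5ap (0.124) and Mki67 (0.114), without IR replicate 3 Cd44 (0.0967) and Selplg (0.0501), and without Sham replicate 3 Cd44 (0.0516).

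The count of 1371 genes rested on few cells in part: it was 644 without BI replicate 1, which held most BI neutrophil-like cells, and 742 without IR replicate 2. With 119 cells drawn from each library it was 232, and with counts thinned to 164754 UMIs it was 114; both settings test fewer genes on fewer counts.

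**Figure D2:**
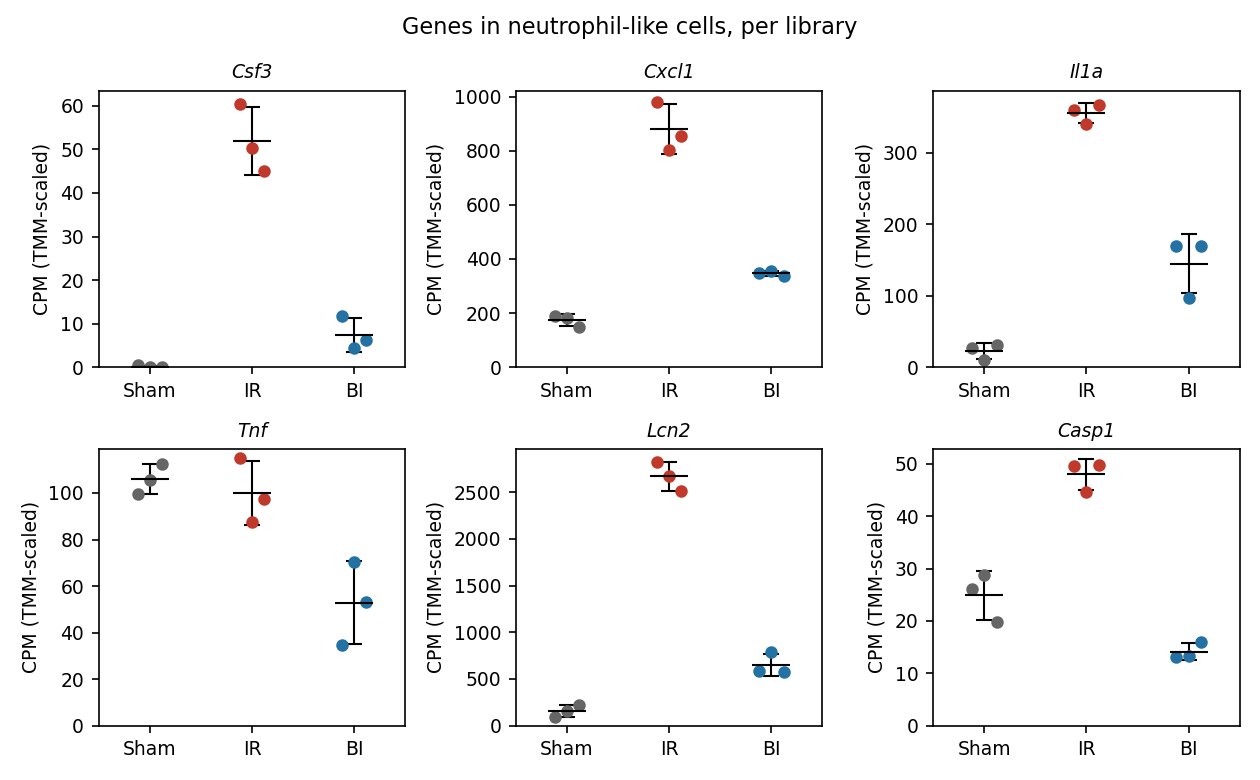
CPM in neutrophil-like cells (vertical axis) of Csf3, Cxcl1, Il1a, Tnf, Lcn2 and Casp1 in each Sham, IR and BI library; points are libraries, with the group mean and SD. Lcn2 averages 157 CPM in Sham, 2668 in IR and 649.5 in BI.

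From Sham to IR the question is what injury did to neutrophils. Neutrophil-like cells of the injured graft carried more RNA of cytokines and NF-kB targets and less of the bone marrow retention receptor Cxcr4: 1857 genes rose and 1849 fell. Cluster 14 held 93.6% of the Sham neutrophil-like cells, and cluster 0 held 76.7% of those in IR and 80.4% in BI. Saal1 (log2FC 7.73, SE 0.343), Retn (7.55), RT1-A2 (7.25), the fatty acid receptor Gpr84 (5.53), thrombospondin Thbs1 (5.46), versican Vcan (4.96), Il6 (4.73) and the cytokine subunit Ebi3 (4.50) rose most. Ly6al (-3.07), Cxcr4 (-3.02, SE 0.160, adjusted p = 5.11e-12), Rgs2 (-2.96), Klf4 (-2.91), Scgb1a1 (-2.89), Fosb (-2.84), Srpk1 (-2.51) and Cdc14a (-2.42) fell most. Vcan and Il6 were also among the top 10 genes of the monocyte-like cluster 1, and Thbs1, scaled to the plain library total, averaged 4653 CPM in monocyte-like and 2005 CPM in neutrophil-like cells of IR. Scgb1a1 is secreted by airway cells and averaged 40479 CPM over all cells in Sham, 4954 in IR and 8783 in BI.

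Of 33 NF-kB targets and cytokines 28 rose and 1 fell from Sham to IR (28 and 1 over the list alone; median log2FC 1.87, adjusted p = 3.58e-17, and adjusted p = 0.0929 with an estimated correlation), led by Ccl3 (3.35), Cxcl3 (4.28), Sod2 (3.04) and Nfkb2 (3.15). Of 18 granule genes 15 rose and 1 fell (adjusted p = 6.26e-09, and adjusted p = 0.141 with an estimated correlation), with Hp (3.77), Lcn2 (4.12), the collagenase Mmp8 (2.22) and Cd177 (2.70). The interferon response rose (18 rose, 1 fell, with 19 and 2 over the list alone, adjusted p = 4.46e-05, and adjusted p = 0.199 with an estimated correlation), with Cxcl10 (3.09) and Mx2 (1.77). Hypoxia and glycolysis rose (18 and 5, adjusted p = 0.000158, and adjusted p = 0.146 with an estimated correlation), with Slc2a1 (1.91) and Ldha (1.61). Oxidative stress genes rose (14 and 3, adjusted p = 0.00182, and adjusted p = 0.204 with an estimated correlation), with Mt1 (2.93) higher and Gsr (-1.64) lower. All 12 mitochondrial-encoded genes fell (median log2FC -1.20; Mt-nd1 -1.54, Mt-nd4 -1.42, adjusted p = 4.46e-05, and adjusted p = 0.286 with an estimated correlation), beside the higher mitochondrial share of the Sham libraries given above. S100a8 rose (1.46, adjusted p = 1.94e-06), as did S100a9 (0.96), while S100a6 fell (-0.75); 3 of 5 RAGE ligands rose and 1 fell (adjusted p = 0.111). The list RAGE ligands in neutrophils, IR minus Sham, passed without Sham replicate 2 (adjusted p = 0.0299) and without Sham replicate 3 (adjusted p = 0.0454). The AGE-RAGE list, again no independent evidence, had 19 members higher and 14 lower (median log2FC -0.08, mean 0.14, test direction upward, adjusted p = 0.393), with Il1a (3.73), Il1b (1.85) and the coagulation factor F3 (2.71) higher. Tnf (-0.08, adjusted p = 0.746) and Ager (-0.21, adjusted p = 0.659) did not pass; their signs turned with equal cell numbers (0.08) and without Sham replicate 1 (1.25). The recruitment (11 and 4, adjusted p = 0.0982), heat shock and immediate early (7 and 13, adjusted p = 0.0673), inflammasome (7 and 5, adjusted p = 0.0907) and eicosanoid lists (3 and 2, adjusted p = 0.724) did not pass. Nor did the class II (2 and 1; median -0.06, mean 0.06, test direction downward, adjusted p = 0.906), cytotoxic (3 and 1, adjusted p = 0.611) and cell cycle lists (0 and 3, adjusted p = 0.408). Adjusted over the list alone, 3 eicosanoid genes rose and 3 fell, 8 inflammasome genes rose and 5 fell, and the other lists gave the counts above.

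BI minus Sham asks how far treated neutrophils stayed from those of an uninjured lung. They still carried Saal1 (log2FC 5.53), Fsip1 (4.95), Thbs1 (4.93), Gpr84 (4.68), Il6 (4.30), Batf (3.90), Vcan (3.85) and the itaconate enzyme Acod1 (3.72) above Sham, and Scgb3a1 (-2.91), Ngp (-2.79), Cxcr4 (-2.79), Ly6al (-2.63), Scgb1a1 (-2.49), Srpk1 (-2.46), Pithd1 (-2.28) and Klf4 (-2.13) below it. Over all cells, Ly6al and Scgb1a1 averaged less in BI than in Sham as well, as given above. In total 1273 genes were higher and 884 lower, and 1420 passed without BI replicate 1. The NF-kB list was higher (27 rose, 2 fell, with 27 and 3 over the list alone, adjusted p = 5.91e-16, and adjusted p = 0.108 with an estimated correlation), with Cxcl3 (3.57) and Nfkb2 (2.56). The granule list was higher too (14 and 2, with 15 and 2 over the list alone, adjusted p = 2.2e-08, and adjusted p = 0.136 with an estimated correlation), with Hp (3.58) and Mmp8 (2.44). So was the hypoxia list (16 and 2, with 16 and 5 over the list alone, adjusted p = 9.76e-05, and adjusted p = 0.136 with an estimated correlation), with Hk1 (1.85). Oxidative stress (13 and 2, adjusted p = 0.00314, and adjusted p = 0.213 with an estimated correlation, Mt1 3.03) and cytotoxic genes (6 and 0, adjusted p = 0.000558, and adjusted p = 0.217 with an estimated correlation, Gzmb 2.23) were higher. The interferon list (11 and 2, adjusted p = 0.0104, and adjusted p = 0.348 with an estimated correlation) was not called without BI replicate 1 (adjusted p = 0.202). Heat shock and immediate early genes (2 and 10, adjusted p = 0.00247, and adjusted p = 0.213 with an estimated correlation, Fosb -1.67) and mitochondrial-encoded genes (0 and 11, adjusted p = 2.2e-08, and adjusted p = 0.213 with an estimated correlation, Mt-nd1 -2.04) were lower. Tnf was below Sham (-1.24, adjusted p = 0.000219), whereas S100a8 (1.31) and S100a9 (0.80) were above it. The AGE-RAGE (15 and 10, adjusted p = 0.070, and 0.0463 without Sham replicate 3), RAGE ligand (3 and 1, adjusted p = 0.0546, but 0.0194 without BI replicate 2, 0.0301 without BI replicate 3, 0.00681 without Sham replicate 2 and 0.0231 without Sham replicate 3), recruitment (11 and 5, adjusted p = 0.0543) and class II lists (3 and 0, adjusted p = 0.0546) did not pass. Nor did the eicosanoid (5 and 3, adjusted p = 0.303), inflammasome (5 and 3; median -0.52, mean 0.01, adjusted p = 0.380) and cell cycle lists (1 and 1, adjusted p = 0.940). Adjusted over the list alone, higher and lower counts were 16 and 10 for AGE-RAGE, 11 and 6 for recruitment, 12 and 2 for interferon, 3 and 13 for heat shock, 14 and 6 for oxidative stress, 5 and 4 for inflammasome and 7 and 0 for cytotoxic genes.

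Set against each other, 895 genes of neutrophil-like cells were called in opposite directions by injury and treatment: 546 rose from Sham to IR and were lower in BI than in IR, and 349 did the reverse. Independent calls would give 180.5 and 161. In the same direction there were 58 and 14. Both contrasts share the IR libraries, which by itself favours opposite signs. With different IR libraries in each contrast, a choice made after seeing the data, 252 to 646 genes were called in opposite directions over 6 ways to part them, where independent calls would give 73.9 to 227, and 16 to 83 in the same direction. In 20 simulations with no difference between BI and IR the count was 0. Such data give almost no calls for BI minus IR, so this result was fixed in advance. It cannot show what the shared IR libraries add among genes that differ. The count was 460 without BI replicate 1, 500 without IR replicate 2 and 436 at an adjusted p of 0.01.

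Monocyte- or interstitial macrophage-like cells of BI expressed more of the chemokine Ccl17, which attracts T cells, and more class II genes, and less of many cytokines. Of 12133 genes, 2279 were higher and 2231 lower in BI than in IR. Ccl17 rose from 134 to 978 CPM (log2FC 2.87, SE 0.226, adjusted p = 8.37e-06), with Defb14 (2.63) and Vps39 (2.60), and Retn fell (-3.93, SE 0.159). Cluster 7 held 54.8% of this class in BI and 23.7% in IR, cluster 1 held 40.7% and 73.3%, and clusters 9 and 13 held 52.6% and 41.2% of it in Sham. Contrasts with Sham therefore compare different clusters, and BI minus IR compares different mixes of clusters 1 and 7. Defb14 was among the top 10 genes of cluster 7, and Csf3, Il6 and Ccl2 among those of cluster 1. Ccl17, RT1-Db1, RT1-Ba, RT1-Bb and RT1-Da were also among the top 10 genes of the dendritic-like cluster 16, whose share rose from 0.694% in IR to 2.10% in BI. Ccl17 averaged 22.2 CPM in T-like cells of BI. Of 14 class II genes 8 rose and 1 fell (9 and 1 over the list alone, adjusted p = 0.00205, and adjusted p = 0.218 with an estimated correlation). Of 28 interferon response genes 15 rose and 2 fell (16 and 4 over the list alone, adjusted p = 0.00223, and adjusted p = 0.218 with an estimated correlation). NF-kB targets fell (22 of 33, with 3 higher; 22 and 4 over the list alone, adjusted p = 1.37e-07, and adjusted p = 0.218 with an estimated correlation), as did hypoxia and glycolysis genes (16 of 30, with 1 higher; 17 and 1 over the list alone, adjusted p = 0.000201, and adjusted p = 0.218 with an estimated correlation). The granule list fell too (14 of 18; the same over the list alone, adjusted p = 1.36e-07, and adjusted p = 0.218 with an estimated correlation), with Mmp8 (-3.74), Pglyrp1 (-3.68) and S100a9 (-3.40) among the largest falls; these are neutrophil genes, and S100a9 over all cells averaged 24361 CPM in IR and 3119 in BI. From Sham to IR 3242 genes rose and 3602 fell in this class, among them Lcn2 (7.89), Csf3 (7.47) and the complement genes C1qc (-3.48) and C1qa (-3.34), which mark resident macrophages. From Sham to BI 2658 rose and 2598 fell, with Saal1 (6.62), Cxcl11 (5.93) and Batf (5.76) higher and Apoe (-3.74) lower.

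In 320 of 7392 genes the BI minus IR effect differed between neutrophil-like and monocyte-like cells (limma, BH), and in 31 of them both effects were called in opposite directions. The signed log2FC was more positive in neutrophil-like than in monocyte-like cells for 223 of the 320, which includes genes that fell in monocyte-like cells alone. Some of the largest differences were those of neutrophil genes that were called lower in monocyte-like cells and not called in neutrophil-like cells, such as Cd177 (difference 3.51), S100a9 (3.31), Mmp9 (3.23), S100a8 (2.92) and Cxcr2 (2.74). S100a9 over all cells averaged 24361 CPM in IR and 3119 in BI. The cytokine Osm rose in neutrophil-like cells (log2FC 0.79) and fell in monocyte-like cells (-0.59), a difference of 1.39 (SE 0.162, adjusted p = 0.0111). The hexokinase Hk3 did the same (0.92 and -1.01), while Irf7 (-0.63 and 0.57; difference -1.25, SE 0.171, adjusted p = 0.0143) and Parp14 (-0.55 and 0.94) fell in neutrophil-like and rose in monocyte-like cells. This count depended on single libraries: it was 0 without BI replicate 3, 0 without IR replicate 2, 7 without IR replicate 1, 61 without BI replicate 2, 90 without IR replicate 3, 96 without Sham replicate 3 and 154 without Sham replicate 1, against 1442 genes at an unadjusted p under 0.05 with all libraries.

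Alveolar macrophage-like cells, the resident phagocytes of the airspace, showed 1601 genes higher and 1503 lower in BI than in IR (12978 tested). Ly6al, a member of the Ly6 surface protein family, averaged 1391 CPM in BI, 1.83 in IR and 939 in Sham (BI minus IR log2FC 9.52, SE 0.393, adjusted p = 7.23e-09); counts of its family are uncertain because members resemble each other. The small heat shock protein gene Hspb1 rose (2.85), and the complement receptor Vsig4 fell (-3.72, adjusted p = 1.03e-08). Of 28 interferon response genes 16 fell and 0 rose (18 and 0 over the list alone, adjusted p = 8.67e-08, and adjusted p = 0.198 with an estimated correlation). Of 33 NF-kB targets 18 fell and 2 rose (22 and 2 over the list alone, adjusted p = 1.99e-05, and adjusted p = 0.320 with an estimated correlation). Pglyrp1 (-3.74), Mmp8 (-3.72) and Cxcr2 (-3.39), all neutrophil genes, fell as well, with the granule list (14 of 18, 0 higher; the same over the list alone, adjusted p = 3.01e-09, and adjusted p = 0.291 with an estimated correlation). The AGE-RAGE list, no independent evidence, had 18 of 77 members higher and 9 lower (19 and 9 over the list alone, adjusted p = 0.0422, and adjusted p = 0.387 with an estimated correlation). The BI minus IR count was 1823 without BI replicate 2 and 1676 without IR replicate 2. From Sham to IR 3831 genes rose and 4364 fell, with Thbs1 (5.89) and Ebi3 (5.83) higher and Fam53c (-4.68), Rasgef1b (-4.53) and Efna5 (-4.43) lower. Here cluster 12 held 94.2% of this class in IR and 86.0% in BI, while clusters 3, 5 and 8 held 41.6%, 33.0% and 21.9% of it in Sham. Clusters 5 and 8 had median mitochondrial shares of 5.49% and 3.89%, against 1.07% in cluster 3, and none of the markers of this class among their top 10 genes. Efna5 was among the top 10 genes of cluster 5, and Fam53c, Rasgef1b and Tex14 among those of cluster 8. Without clusters 5 and 8, left out after seeing the data, 4361 genes passed. From Sham to BI 2989 rose and 3431 fell (RT1-A2 4.60, Tex14 -4.53).

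T- and NK-like cells of IR held more RNA of interferon response genes than those of Sham, and more neutrophil RNA as well. In B-like cells 9 of 24 interferon genes rose from Sham to IR and 0 fell (11 and 0 over the list alone, adjusted p = 0.000150, and adjusted p = 0.155 with an estimated correlation). Cluster 2 held 98.9% of T-like cells in Sham, and cluster 10 held 97.7% of them in IR and 96.1% in BI, so contrasts with Sham compare different clusters in this class. From Sham to IR, 17 of 25 interferon genes rose in T-like cells and 0 fell (20 and 0 over the list alone, adjusted p = 1.41e-15, and adjusted p = 0.0156 with an estimated correlation). In the same contrast 21 of 26 rose in NK-like cells (22 over the list alone, adjusted p = 8.06e-20, and adjusted p = 0.0188 with an estimated correlation). Scaled to the plain library total, S100a9 rose from 170 CPM in Sham to 2162 in IR in T-like cells and from 367 to 3776 in NK-like cells, and Ifit2, Rsad2, Mx2 and Ifit3 were among the top 10 genes of the neutrophil-like cluster 29. Choices made after seeing the data left out interferon genes at the level of free RNA. They select genes by their IR level in the class, and IR is also a side of both contrasts tested. This favours genes that are high in IR, so the counts that remain do not exclude free RNA. Among genes with an IR level of at least 0.25 of that over all cells, 12 of 20 rose in T-like cells (adjusted p = 1.34e-10, and adjusted p = 0.0496 with an estimated correlation) and 19 of 24 in NK-like cells (adjusted p = 8.16e-18, and adjusted p = 0.0124). Among genes at or above their level over all cells, 6 of 9 rose in NK-like cells (adjusted p = 3.9e-06, and adjusted p = 0.0252), 1 of 6 in T-like cells (adjusted p = 0.0332, and adjusted p = 0.246) and 1 of 5 in B-like cells (adjusted p = 0.985). From IR to BI, 13 of 26 fell in NK-like cells and 0 rose (18 and 0 over the list alone, adjusted p = 9.79e-14, and adjusted p = 0.0613 with an estimated correlation). In the same comparison 5 of 25 fell in T-like cells with 1 higher (the same over the list alone, adjusted p = 4.8e-05, and adjusted p = 0.0844 with an estimated correlation). Among genes at or above their level over all cells, 5 of 9 fell in NK-like cells (adjusted p = 1.16e-05, and adjusted p = 0.0613 with an estimated correlation). In T-like cells 1 of 6 fell with 1 higher (adjusted p = 0.251, and adjusted p = 0.527 with an estimated correlation). Mitochondrial-encoded genes were lower in BI than in IR in T-like (10 of 13; 12 over the list alone, adjusted p = 1.17e-08, and adjusted p = 0.186 with an estimated correlation) and NK-like cells (11 of 12; 12 over the list alone, adjusted p = 1.11e-15, and adjusted p = 0.0743 with an estimated correlation). BI against IR gave 765 genes higher and 884 lower in T-like cells, 450 and 588 in NK-like cells and 354 and 482 in B-like cells. Vps39 rose in T-like (log2FC 3.37) and NK-like cells (2.26), as in monocyte-like cells, and Lrrc8b (2.44) and Zmynd8 (2.07) in B-like cells. RT1-A2 rose from Sham to IR by log2FC 7.04 in T-like, 6.82 in NK-like and 6.24 in B-like cells. Here too a strain or donor difference stays open, as for Vps39 (compare Ly6al below).

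Neutrophil genes were among the largest falls in these cells from IR to BI: Mmp8 (-3.59), Pglyrp1 (-3.54) and Cxcr2 (-3.40) in T-like cells, Stfa2l3 (-4.44) and Cxcr2 (-3.77) in NK-like cells, and Lcn2 (-3.74), Trem1 (-3.65) and Camp (-3.54) in B-like cells. Of 17 granule genes 15 fell in T-like cells and 0 rose (the same over the list alone, adjusted p = 2.32e-16, and adjusted p = 0.0844 with an estimated correlation). At least 1 UMI of S100a9 was found in 99.6%, 97.3% and 94.3% of T-like cells of the IR libraries (median depths 2545, 3074.5 and 3202.5 UMIs), in 77.9%, 30.6% and 50.1% in BI and in 35.0%, 22.7% and 27.5% in Sham, although T cells should lack this gene. Leaving out genes at the level of free RNA gave 1351 calls in T-like, 833 in NK-like and 701 in B-like cells. The counts also moved with single libraries: T-like 1066 without BI replicate 2 and 839 without IR replicate 2, NK-like 658 and 570 without the same libraries, and B-like 421 without BI replicate 2, 548 without BI replicate 3, 548 without IR replicate 1 and 507 without IR replicate 2.

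Endothelial-like cells of IR held more RNA of NF-kB targets and hypoxia genes than those of Sham. Those of BI held less RNA of NF-kB targets than those of IR. Neutrophil RNA in these cells, given below, changed in the same directions. The lists were not tested here without genes at the level of free RNA, so that source is not excluded. From Sham to IR, 25 of 32 NF-kB targets rose and 1 fell (25 and 2 over the list alone, adjusted p = 2.46e-20, and adjusted p = 0.00681 with an estimated correlation). Of the hypoxia genes 10 of 26 rose and 0 fell (11 and 0 over the list alone, adjusted p = 4.01e-07, and adjusted p = 0.00681 with an estimated correlation). Gimap7, Palmd, Arhgef15 and Hdac7, which had no UMI in IR, were at least 7.17-, 5.35-, 7.18- and 12.7-fold lower. In total 593 genes rose and 585 fell. In BI against IR 228 genes were higher and 250 lower of 7733. Hdac7, a histone deacetylase, was at least 7.34-fold higher and Adamtsl2 at least 7.07-fold, and 10 of 32 NF-kB targets fell with 0 higher (13 and 0 over the list alone, adjusted p = 2.22e-09, and adjusted p = 0.0243 with an estimated correlation). Olfm4 (-5.52), Stfa2l3 (-4.95) and Cxcr2 (-4.64), neutrophil genes, fell; S100a9 averaged 12304 CPM in these cells in IR and 660 in BI. Against Sham, BI endothelial-like cells still held Selp, the platelet and endothelial selectin, at 325 against 6.71 CPM (log2FC 5.61, SE 0.457, adjusted p = 1.54e-11) and Angptl4 (5.09), with Ccl21 (-4.47) and the venous regulator Nr2f2 (-2.90) lower (931 genes higher, 753 lower). IR libraries held only 22 to 35 endothelial-like cells: 233 genes passed in BI against IR without IR replicate 1 and 180 without IR replicate 2, and 1087 in BI against Sham without Sham replicate 3. The share of calls higher in BI than in IR was 47.7%, against 31.4% with RLE factors (median of all genes shifted by -0.14) and 25.6% with DESeq2.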

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

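Chosen after the results were seen were the comparison of free RNA with all cells, the Ly6al counts in alveolar type 2-like cells, the ratio of Ly6al to all cells, the ratio of neutrophil-like to all other cells the trimmed NK- and B-like cells and, between Ly6al-positive and other cells, the genes besides RT1-A2.

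The BI minus IR effect differed between neutrophil-like and monocyte-like cells in 320 genes. As given above, this count depended on single libraries and was 0 without BI replicate 3, which ends the calls of Osm and Irf7 too. For Osm the effect in neutrophil-like cells exceeded that in monocyte-like cells by 1.39 on the log2 scale (SE 0.162, adjusted p = 0.0111), and for Irf7 the difference was -1.25 (SE 0.171, adjusted p = 0.0143). Cluster 20, left unnamed because of its doublet calls, held a mean of 1.35% of BI cells (SD 0.360), 1.01% of IR cells (SD 0.632) and 0.313% of Sham cells (SD 0.193), and this difference was not tested. Its 693 kept cells had Adgre4 and Rap1gap2 among their top genes, and doublet calls, removed before, made up 28.9% of the cluster.

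Neutrophil genes were lower in BI than in IR in T-, NK- and B-like cells. If free RNA from neutrophils were the cause, these genes would follow their level over all cells. Over 11 markers, 31 of 31 values were lower and called, and their log2FC differed from those over all cells by a median of 0.344 (SE 0.0881), which is consistent with that source. Neutrophils counted among T-like cells were argued against as the whole cause by the S100a9 UMIs in at least 94.3% of T-like cells of every IR library, since a few wrong cells would leave the others without them. In NK- and B-like cells some cells did hold much of this RNA: the top 5% of cells held 48.2% to 50.1% of S100a9 UMIs of NK-like cells in IR libraries and 17.8% to 46.7% in B-like cells, and cluster 44 held 74.1% of those of B-like cells in IR replicate 1. Without the 25% of cells with the largest share of neutrophil marker UMIs in each library, the median log2FC of 10 markers was still -3.17 (SE 0.187) in NK-like and -3.18 (SE 0.216) in B-like cells, with 10 of 10 lower and called in each, which argues against such cells as the whole cause there too. A change within the lymphocytes themselves was not tested.

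Ly6al was near 0 in alveolar macrophage-like cells of IR and high in BI and Sham. A variant that removes its counts in all cells of the IR animals would leave no IR class above T-like cells. A UMI was found in 25% of alveolar type 2-like cells of IR (7 of 28, exact 95% interval 10.7% to 44.9%, median 3279 UMIs). In T-like cells it was 0.386% (4 of 1035, median 3074.5 UMIs, two-sided Fisher's exact p = 1.22e-09 over cells pooled from the libraries). This decides nothing, since the family member Ly6i was among the top 10 genes of the alveolar type 2-like cluster 33. Reads of Ly6i counted as Ly6al were not tested. Free RNA from other cells was argued against by a level at least 3.85 times that over all cells in every BI library. A strain or donor difference between the animals cannot be told apart from treatment, because both would follow the groups, with at least 50.2% of cluster 12 cells positive in each BI library. Cells of 2 genotypes mixed in BI stay open too. In cluster 12, RT1-A2 was lower in cells with at least 3 UMIs of Ly6al than in cells with none in all 3 BI libraries (log2 ratios -0.81, -0.55 and -0.41), between the limits set in advance. RT1-A1 (-0.84, -0.92 and -0.85), Vps39 (-1.38, -2.47 and -1.65) and RGD1560281 (-2.52, -2.24 and -2.34) were lower as well.

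For the lower share of neutrophil-like cells in BI than in IR, the 1000-UMI minimum of the barcodes stays open. Over cells of at least 2000 UMIs the log2FC was -3.10 against -2.57, the direction a depth minimum would give, and the median UMIs of neutrophil-like cells were 1487.5 to 1949 in BI libraries and 2266 to 2621 in IR libraries. The shift was under the SE of 0.745, the limit set in advance, but that is the error between libraries and not of the shift, so it decides nothing. The BI to IR ratio of neutrophil-like cells over that of all other cells, 0.0962, restates the lower share and says nothing on recovery, since equal recovery of all classes leaves shares as they are. Loss of neutrophils alone during digestion and an effect of baicalein stay open and untested.

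Other groupings of the libraries were run for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in all that follow 1 of 10 splits, the real one, gave as large a count. All counts of 10 splits were fitted on the 6 libraries compared. For class shares the real counts were 11 (BI against IR), 16 (IR against Sham) and 6 (BI against Sham, against 5 in the fit of all 9 libraries), and the highest of the other splits gave 0. For genes of neutrophil-like cells they were 1672, 4043 and 1617 in the same order, and the highest other was 1, 0 and 0. In monocyte-like cells they were 4574, 6651 and 4842, in alveolar macrophage-like cells 2666, 8734 and 6406, in T-like cells 1352, 1518 and 2367, in NK-like cells 845, 1564 and 1941, in B-like cells 633, 934 and 1456, and in endothelial-like cells 303, 1062 and 1876. In dendritic-like cells they were 239, 1353 and 1275, in airway-like cells 112, 1270 and 1414, in erythroid-like cells 217, 659 and 183, and in plasmacytoid dendritic-like cells 553 for IR against Sham. The difference between neutrophil- and monocyte-like cells gave 98 genes on 6 libraries, with 0 as the highest other. For the genes called in opposite directions, 100 splits of the 9 libraries could be drawn. Of these, 1 gave as many as 895, and the highest other gave 94. A random grouping of the libraries thus seldom gives this count. Splits that mix the groups call few genes in either contrast, so they show that the groups differ and not an excess of opposite calls. Each of these splits also has a group shared by both contrasts, but with few calls this cannot show what sharing adds.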

How the results depend on the processing

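All alternatives of the other classes and of the difference between classes that leave out a library, estimate a correlation or add a block were chosen after seeing the data, as were the denominator without neutrophil-like cells, the fit without clusters 5 and 8, shares with these clusters unnamed, different IR libraries in each contrast and interferon lists without genes at the level of free RNA. Of 778 values of the main results, counts of genes, classes or lists and the neutrophil-like share, 639 kept to the main one, which for a count means within 1.5-fold and for the share the same direction and call. Of 667 values of class shares 605 kept theirs, 53 lost a call and 9 turned. Of 381 values of gene lists 324 kept theirs, 42 lost a call, 12 gained one and 3 turned. Of 3058 values of named genes 2866 kept theirs, 166 lost a call, 3 gained one and 23 turned. Replicate numbers do not pair the samples: within-group residuals of the same number correlated between -0.132 and 0.098 over all cells, and each library correlated best with its own number in only 2 of 9 cases (4 in neutrophil-like and 3 in monocyte-like cells). Where a setting holds fewer cells, counts or genes the smaller count follows from that, and otherwise the cause was not tested.

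With equal cell numbers, which leave fewer cells, neutrophil-like cells gave 232 genes for BI minus IR, 1055 for IR minus Sham and 771 for BI minus Sham. With thinned counts they gave 114, 841 and 677. With equal cells the log2FC turned for Cybb (0.19) in BI minus IR, RT1-DMa (-0.11) and Tnf (0.075) in IR minus Sham, and Mapk14 (0.077), RT1-Ba (-0.0043) and RT1-Db1 (-0.12) in BI minus Sham. With thinned counts it turned for Cybb (0.029), Icam1 (0.23), S100a8 (0.047), S100a9 (0.029) and Tnf (0.32) in BI minus IR, and for RT1-Ba (-0.039), RT1-Bb (-0.085) and RT1-Db1 (-0.19) in BI minus Sham. These settings moved the median of all genes by 0.15 and 0.18 in BI minus IR.

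With DESeq2, mast-like cells gave 22 genes for BI minus IR and plasmacytoid dendritic-like cells 262 for BI minus Sham. With RLE factors mast-like cells gave 6. With no filter on low counts, which tests more genes, airway-like cells gave 547 (BI minus IR), 1408 (IR minus Sham) and 1489 (BI minus Sham), erythroid-like cells 174 for BI minus IR, and mast-like cells 58 for BI minus IR and 297 for IR minus Sham. A fit of the 6 libraries compared, which holds fewer samples, gave 112 and 1414 in airway-like cells (BI minus IR and BI minus Sham), 303 in endothelial-like and 0 in mast-like cells (BI minus IR; edgeR, with 458 genes at an unadjusted p under 0.05 in all libraries). With a replicate block the difference between classes gave 94 genes, and mast-like cells gave 0, 37 and 207 for BI minus IR, IR minus Sham and BI minus Sham. Without clusters 5 and 8, which leaves fewer cells, alveolar macrophage-like cells gave 4361 genes for IR minus Sham. At an adjusted p of 0.01, 436 genes were called in opposite directions. With different IR libraries in each contrast, of which fewer stand in each, the count was 646, 448 and 608 with IR replicate 1, 2 or 3 alone against Sham and the other 2 against BI, and 580, 252 and 313 with IR replicate 1, 2 or 3 alone against BI.

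With TMM factors over the class counts, 7 classes passed in IR minus Sham, 4 higher and 3 lower, and 8 in BI minus IR, 2 higher and 6 lower. The log2FC turned in BI minus IR for NK-like (-0.30), T-like (-0.083), airway-like (-0.92), alveolar type 1-like (-0.40) and dendritic-like cells (-0.56), and in IR minus Sham for NK-like (0.47), alveolar type 1-like (0.41), dendritic-like (0.78) and plasmacytoid dendritic-like cells (0.63). Without neutrophil-like cells in the denominator 6 classes passed in BI minus IR. With immune cells alone 5 passed in BI minus IR, 9 in IR minus Sham and 3 in BI minus Sham.

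With an estimated correlation 0 lists passed in neutrophil-, monocyte-, alveolar macrophage- and B-like cells in every contrast, in T- and NK-like cells in BI minus IR and BI minus Sham, and in endothelial-like cells in BI minus Sham. It left 4 lists in each of T- and NK-like cells for IR minus Sham and in endothelial-like cells for BI minus IR and IR minus Sham. The interferon list in B-like cells, IR minus Sham, turned with genes under their level over all cells left out (adjusted p = 0.985, and 0.990 with an estimated correlation). With fry 13 lists passed in neutrophil-like cells in IR minus Sham and 13 in BI minus Sham.

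Leaving out 1 library at a time, neutrophil-like cells gave 644 to 1753 genes for BI minus IR (644 without BI replicate 1, 742 without IR replicate 2) and 1420 to 2336 for BI minus Sham (1420 without BI replicate 1). Opposite calls ranged from 460 to 1128 (460 without BI replicate 1, 500 without IR replicate 2). The difference between classes ranged from 0 to 413 (0 without BI replicate 3 or IR replicate 2, 7 without IR replicate 1, 61 without BI replicate 2, 90 without IR replicate 3, 96 without Sham replicate 3, 154 without Sham replicate 1). Classes past the threshold in BI minus Sham ranged from 3 to 6 (3 without BI replicate 1, BI replicate 3 or Sham replicate 2), and the neutrophil-like share in BI minus Sham from 0.50 to 2.29 (2.29, adjusted p = 0.0487, without Sham replicate 1). Alveolar macrophage-like cells gave 1676 to 3208 for BI minus IR (1823 without BI replicate 2, 1676 without IR replicate 2). T-like cells gave 839 to 1823 for BI minus IR (1066 without BI replicate 2, 839 without IR replicate 2) and NK-like cells 570 to 1162 (658 and 570 without the same libraries). B-like cells gave 421 to 878 for BI minus IR (421 without BI replicate 2, 548 without BI replicate 3, 548 without IR replicate 1, 507 without IR replicate 2), 595 to 1087 for IR minus Sham (602 without Sham replicate 1, 595 without Sham replicate 3) and 772 to 1542 for BI minus Sham (789 without BI replicate 3, 817 without Sham replicate 1, 772 without Sham replicate 3). Endothelial-like cells gave 180 to 447 for BI minus IR (233 without IR replicate 1, 180 without IR replicate 2), 757 to 1299 for IR minus Sham (760, 757 and 768 without IR replicates 1, 2 and 3) and 1087 to 1980 for BI minus Sham (1087 without Sham replicate 3).

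Dendritic-like cells gave 151 to 397 for BI minus IR (217 without BI replicate 3, 211 without IR replicate 1, 151 without IR replicate 2) and 771 to 1475 for IR minus Sham (771 without Sham replicate 3). Plasmacytoid dendritic-like cells gave 119 to 327 for BI minus IR (124 without BI replicate 1, 119 without BI replicate 3, 165 without IR replicate 1, 168 without IR replicate 2), 401 to 643 for IR minus Sham (401 without IR replicate 1, 410 without Sham replicate 3) and 168 to 492 for BI minus Sham (190 without BI replicate 1, 168 without BI replicate 3, 250 without Sham replicate 1, 221 without Sham replicate 3). Airway-like cells gave 42 to 442 for BI minus IR (62 and 185 without BI replicates 2 and 3, 42 and 170 without IR replicates 1 and 2, 210, 200 and 192 without Sham replicates 1, 2 and 3), 439 to 1023 for IR minus Sham (439, 484 and 468 without Sham replicates 1, 2 and 3) and 395 to 1161 for BI minus Sham (560 without BI replicate 1, 395, 433 and 473 without Sham replicates 1, 2 and 3). Erythroid-like cells gave 99 to 295 for BI minus IR (173 and 99 without BI replicates 1 and 3, 111 and 131 without IR replicates 1 and 2) and 115 to 228 for BI minus Sham (115 without BI replicate 3, 122 without Sham replicate 1). Mast-like cells gave 0 to 57 for BI minus IR (1 and 6 without BI replicates 1 and 3, 0 and 57 without IR replicates 2 and 3, 0 without Sham replicate 2 or 3), 55 to 264 for IR minus Sham (69 without IR replicate 2, 55 and 101 without Sham replicates 1 and 3) and 205 to 545 for BI minus Sham (205 without BI replicate 1, 270 without Sham replicate 1).

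Some uncalled values turned too. Ager in IR minus Sham ranged from -0.63 to 1.25 (1.25 without Sham replicate 1), Mapk14 in BI minus Sham from -0.14 to 0.11 (0.11 without Sham replicate 3, and above 0 without BI replicate 2 or 3), Nfkb1 in BI minus IR from -0.062 to 0.087 (-0.062 without BI replicate 2, and below 0 without IR replicate 2, Sham replicate 1 or Sham replicate 2) and Stat3 in BI minus IR from -0.016 to 0.26 (-0.016 without IR replicate 1). The adjusted p of the AGE-RAGE list in BI minus IR ranged from 0.511 to 0.974, and its direction turned without IR replicate 1 (0.974).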

Other observations

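Dendritic-like cells of both grafts held more RNA of Cxcl11, an interferon-induced chemokine that attracts T cells, than those of Sham lungs. It averaged 0.994 CPM in Sham, 139 in IR and 224 in BI (IR minus Sham log2FC 6.91, SE 0.840, adjusted p = 9.16e-06, and BI minus Sham 7.63). Monocyte-like cells held it as well, at 3.41, 94.3 and 210 CPM in the same order. Scaled to the plain library total, Cxcl11 averaged 134 CPM in dendritic-like, 0.783 in T-like and 32.9 in all cells of IR, and 207 (25.9 to 385 over libraries), 3.63 and 78.8 CPM in BI. Monocyte RNA in droplets named dendritic-like was not tested. The cytokine subunit Ebi3 rose too (5.69 and 4.83) and stood at its level over all cells in both grafts (626 and 629 CPM in IR, 321 and 330 in BI, on the same scale), while the adhesion molecule Icam2 fell from Sham to IR (-3.43) and the chemokine receptor Ccr2 was lower in BI than in Sham (-2.09). Of 6483 genes, 173 were higher and 181 lower in BI than in IR, 685 and 482 in IR against Sham, and 783 and 425 in BI against Sham. Among the falls from IR to BI were the neutrophil genes S100a9 (-3.80) and Mmp8 (-3.96), and 295 genes passed in BI against IR once genes at the level of free RNA were left out. Without BI replicate 3, IR replicate 1 or IR replicate 2 the BI against IR count was 217, 211 and 151, and without Sham replicate 3 the IR against Sham count was 771.

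Airway epithelial-like cells of IR expressed Calcb, which encodes a calcitonin gene-related peptide, at 185 CPM on 278 UMIs, against 2 UMIs in Sham and 16.3 CPM in BI (BI minus IR log2FC -3.33, SE 0.560, adjusted p = 0.00634). The aldo-keto reductase Akr1b10 was higher in BI than in Sham (4.21). In this class 96 genes were higher and 226 lower in BI than in IR. The count of 322 was 62 and 185 without BI replicates 2 and 3, 42 and 170 without IR replicates 1 and 2, and 210, 200 and 192 without Sham replicates 1, 2 and 3. Plasmacytoid dendritic-like cells (BI with 2 libraries) gave 90 higher and 168 lower, with the thrombin receptor F2r higher (2.28), and erythroid-like cells gave 129 and 135. Without BI replicate 1, BI replicate 3, IR replicate 1 or IR replicate 2 the plasmacytoid dendritic-like count was 124, 119, 165 and 168, and the erythroid-like count 173, 99, 111 and 131. Mast- or basophil-like cells (BI and IR with 2 libraries each) gave 2 higher and 0 lower by edgeR, Cdk6 (4.07) and Bco1 (3.52), with 458 genes at an unadjusted p under 0.05, 22 by DESeq2, 6 with RLE factors and 58 with no filter on low counts. With a replicate block, a fit of the 6 libraries, or without IR replicate 2, Sham replicate 2 or Sham replicate 3 the count was 0, without BI replicate 1 it was 1, without BI replicate 3 it was 6 and without IR replicate 3 it was 57. The mast cell protease gene Mcpt1l4 was at least 12.7-fold lower in IR than in Sham in these cells, and Ggt1 at least 17.2-fold higher. Cluster 22, which no marker set named, expressed Il5, Gata3, Il1rl1 and Hpgds and held a mean of 1.11% of BI cells (SD 0.367), 0.324% of IR cells (SD 0.150) and 1.02% of Sham cells (SD 0.149), a difference that was not tested.

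Gene lists were counted over other splits of the libraries as well, on the 6 libraries compared, where 10 splits are too few for a share under 0.05. Counts of splits with as many lists, the real one included, follow for BI against IR, IR against Sham and BI against Sham in that order. In neutrophil-like cells 1, 6 and 2 splits gave as many (real 8, 6 and 8 lists, highest other 5, 8 and 10). In monocyte-like cells 1, 4 and 7 did (real 8, 6 and 4, highest other 6, 7 and 6). In alveolar macrophage-like cells 3, 7 and 2 did (real 10, 8 and 7, highest other 10, 11 and 10). In T-like cells 2, 1 and 5 did (real 10, 12 and 4, highest other 10, 9 and 7), and in NK-like cells 2, 1 and 6 (real 12, 11 and 4, highest other 12, 10 and 6). In B-like cells 2, 3 and 3 did (real 10, 8 and 4, highest other 10, 8 and 6), and in endothelial-like cells 1, 2 and 2 (real 9, 9 and 5, highest other 6, 10 and 7). Splits that call as many lists as the real grouping point to a structure of the samples shared by genes of a list, which a preset correlation does not take up.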
